A study of Mus musculus with 7 samples.

How the data were processed

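RNA-seq was deposited for 6 samples of mpkDCT4a, an established mouse cell line (clone 4a of a distal convoluted tubule line), and a list of HNF1B ChIP-seq peaks for 1 further sample. For the RNA-seq, 3 samples had been transfected with non-targeting siRNA (siMock) and 3 with a pool of siRNAs against Hnf1b (siHNF1B), with 100 pmol of siRNA and harvest 48 h later. Per the labels' protocols, libraries came from total RNA after removal of ribosomal RNA, with 11 cycles of PCR and paired-end reads of 50 bp. The ChIP-seq sample was untreated cells precipitated with an antibody against HNF1B, with 15 PCR cycles. The series text says that the ChIP-seq data were taken over from another deposited sample, so it is open whether those cells were grown beside the RNA-seq cells. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

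The RNA-seq table holds raw counts per Ensembl gene, deposited by the authors as whole numbers with 1 column per sample. HISAT2, HTSeq, SAMtools, DESeq2, CASAVA 1.4 and MACS2 are named in the submitters' processing notes, without a role for each, and the builds named there are mm10 and mm9. The strand setting and the annotation release are not given in the sources used here, so reads of a gene and an antisense partner cannot be told apart, and genes with near-identical relatives may share reads. The table has 55487 gene rows, every one with an Ensembl identifier and a name, and 114 of the names stand on more than 1 row. It has no rows for unassigned reads. A stray number beside the Gapdh row was not used. Of the identifiers, 55141 were also in a table of Ensembl identifiers and symbols. Gene positions on mm10 were taken by symbol from the RefSeq genes of GRCm38.p6, which gave a position for 11637 of the 12143 genes tested.

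The peak list gives position and score for each peak of the 1 ChIP-seq sample. The deposited score was read as the −log10 of a q-value, because its lowest value of 3.28 lies above the −log10 of the threshold of 0.001 carried in the peak names. That reading comes from the values. The peak coordinates are on mm9, since the last peak of chromosome 7 ends at 152294163, 6.97 Mb beyond the last RefSeq gene of mm10. No genome and no mm9 annotation were used here, so peaks were not assigned to genes, to promoters, exons or introns, or searched for the HNF1 motif, and no peak position is set against a gene position. Peaks and genes are compared only by whole chromosomes and by broad parts of chromosomes 4 and 9, whose bounds are not exact between the builds.

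Library totals ran from 480835 to 12857871 counts, and 3 counts, taken as the floor of detection, correspond to between 0.234 and 6.26 CPM (counts scaled to a common library total). Floors and intervals cover counting error only, since reads amplified by PCR are not independent molecules. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter with the group factor, and the robust quasi-likelihood F test with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 12143 genes kept, and a gene was called at an adjusted p below 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-normalized CPM, as mean ± SD over 3 samples. A fitted fold change gives more weight to deeply sequenced libraries than such a mean does, so the ratio of the means can differ from it. Where a gene had 1 to 3 counts in all libraries of a group together, the ratio of the pooled normalized counts is given with its exact (Clopper-Pearson) 95% interval.

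Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Fry was run beside it. Fry asks whether the genes of a list move one way on balance. There were 27 lists: HNF1B literature targets, apical-basal polarity, planar cell polarity, tight junction, epithelial identity, mesenchymal and EMT, primary cilium and cystic disease, distal convoluted tubule transport, markers of the proximal tubule, thick ascending limb, collecting duct principal cells, intercalated cells, fibroblasts, immune cells and endothelium, kidney developmental transcription factors, cholesterol synthesis, interferon response, NF-kB and inflammatory, p53 targets, cell cycle, canonical Wnt targets, ER and amino acid stress, glycolysis and glucose transport, mitochondrially encoded, immediate early, and reference genes. Adjustment was over the 26 lists with at least 2 tested members for camera, and over all 27 lists for fry. The series title names cell polarity, so the apical-basal polarity list follows the study and is not independent evidence. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took Hnf1b. Among called genes with no overlap between the groups and a mean of at least 1 CPM in the higher group, it took the 10 largest falls and the 10 largest rises. In each list it took up to 4 called members with the largest change, or the 2 most abundant members where none was called. Where 5 or fewer members of a list moved in a direction, the remaining ones are also named, and these were chosen after their values were seen. Genes known only by a predicted or clone name are counted but not named. The part of the rule for genes near a peak was not applied.

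The test was tried on simulated counts for this comparison, drawn from the real means and library totals with 200 genes changed, in 10 runs of 11893 to 11925 genes. With dispersions drawn on the fitted trend, it called 75% of genes changed 1.5-fold, 92% of those changed 2-fold and 99.8% of those changed 4-fold, and 4.83% of its calls were false. With gene-wise dispersions in runs of 11896 to 11925 genes the corresponding shares called were 71%, 90.5% and 99.8%, and 13.7% of the calls were false. The simulated libraries of high and low total did not differ in composition, whereas 1659 genes differed so in the data. Fewer genes were also changed than the 2717 called in the data, so these shares need not hold there. Of 200 simulated lists of unchanged genes, camera gave a p below 0.05 for 0 and 3 respectively, and for 50 of 50 lists of raised genes in either setting. Genes were simulated independently of one another, so these lists do not test camera on correlated genes. The lists called below had estimated correlations of 0.013 to 0.92.

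No pair of libraries differed by so little as sampling noise alone would give (lowest chi-square per gene 1.19). The alternatives tried were RLE normalization, library totals only, no count filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma voom, a replicate block, each replicate left out, an adjusted p below 0.01, a 1.5-fold minimum, mitochondrial genes and the 10 most abundant genes left out, an estimated inter-gene correlation, and the upper part of the peaks by score. Alternatives chosen after the library totals were seen were a depth term in the model, fits within the 3 libraries with the highest totals (deep) or the 3 with the lowest (shallow), and thinning of the deep libraries to the smallest total. With 1 sample left in a group, that sample is assumed to vary like the other group. For chromosome medians of RNA, the mean CPM of siMock was taken as log2(CPM + 0.1). Peaks were summarised with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.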

Results

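Transcript levels were measured by RNA-seq in mpkDCT4a cells after knockdown of Hnf1b, which encodes the homeodomain transcription factor HNF1β of the kidney tubule, and set against cells given non-targeting siRNA. There were 3 siMock and 3 siHNF1B samples. A list of HNF1B binding peaks from untreated cells accompanied them. The series title places the question in the control of cell polarity in kidney cells. Depth differed widely between libraries, within both groups and unequally between them. In siMock the totals were 480835, 12387805 and 554921 counts for replicates 1, 2 and 3. In siHNF1B they were 12857871, 11490132 and 536266 counts. Thus 1 siMock and 2 siHNF1B libraries were deep, and 2 siMock and 1 siHNF1B library were shallow. Genes with at least 1 count numbered 19995 to 20157 in the deep libraries and 12663 to 12974 in the shallow ones. The shallow libraries also differed in composition. The small nuclear RNA Rn7sk took 0.604% to 0.641% of their counts and 0.0746% to 0.0905% of the counts of the deep libraries.

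Hnf1b (ENSMUSG00000020679; mm10 chromosome 11, 83850209 to 83905917) was lower in every siHNF1B library than in any siMock library. Its level was 124 ± 37.3 CPM (SD, n = 3) in siMock and 44.7 ± 9.68 CPM (SD, n = 3) in siHNF1B. The log2 fold change was −1.52 (SE 0.149), a 2.87-fold fall, with an adjusted p of 5.61e-07 by edgeR's quasi-likelihood test. Within the deep libraries the log2 fold change was −1.67 and within the shallow ones −1.65.

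**Figure D1:**
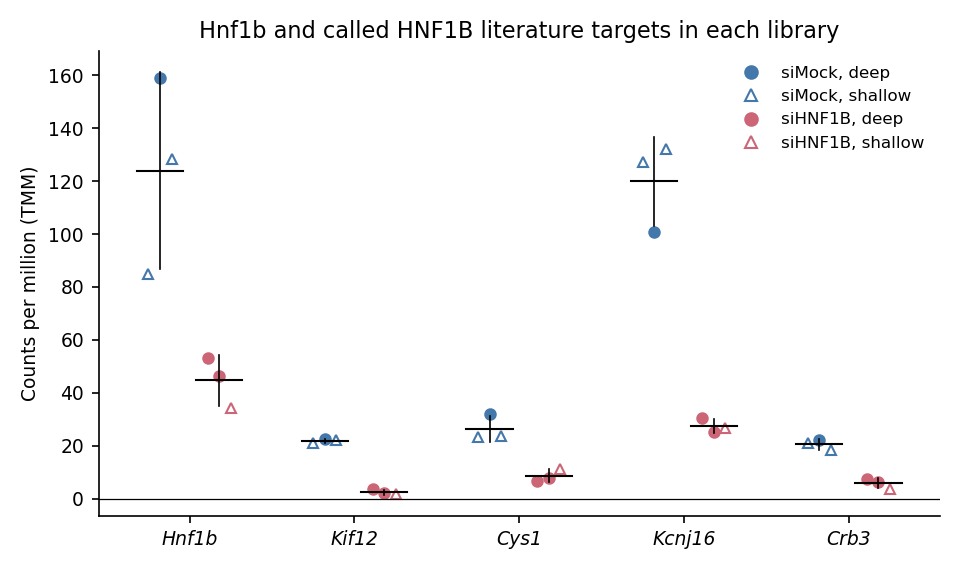
CPM (TMM-normalized) of Hnf1b and of 4 HNF1B literature targets in each library. Points are libraries (filled circles deep, open triangles shallow), horizontal bars are means and vertical bars ± 1 SD of 3 libraries, and for each gene the siHNF1B points lie below the siMock points.

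Knockdown went with changes in a large part of the expressed genes, in both directions. Of 12143 genes tested, 2717 (22.4%) were called, of which 1369 were lower and 1348 higher after knockdown. The change was at least 2-fold for 539 of them, with 251 lower and 288 higher. The levels of 3474 genes (28.6%) did not overlap between the groups, where chance gives 10%. The number called was 1522 without siMock replicate 2, 654 without siHNF1B replicate 1 and 613 without siHNF1B replicate 2, each of them a deep library. With DESeq2 on all 6 libraries it was 770. Within the deep libraries alone 4861 genes were called and within the shallow ones 590. Of the 2117 called genes testable in both depth classes, 2027 (95.7%) had the same sign in both, with r = 0.87 across these genes. Those genes were called from the same libraries, which favours such agreement. Of 3899 genes called within the deep libraries and tested in both, 3440 (88.2%) had the same sign in the shallow ones, and across all 8721 genes tested in both classes r was 0.68 and rho 0.63. Genes are not independent replicates.

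**Figure D2:**
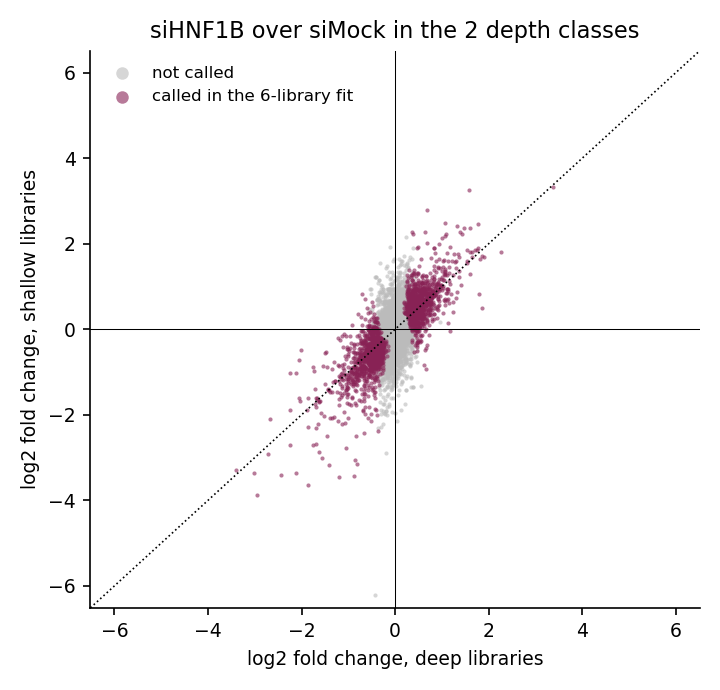
Log2 fold change (siHNF1B over siMock) of 8721 genes in the deep libraries (x axis) and in the shallow libraries (y axis), with genes called from all 6 libraries in purple and the others in grey. The dotted line marks equal values, and r is 0.68 across all genes shown. Of the genes called within the deep libraries alone, 88.2% have the same sign on both axes.

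Among the 10 largest falls, Slc47a1, which encodes the multidrug and toxin extruder MATE1 (ENSMUSG00000010122; mm10 chromosome 11, 61343400 to 61378842), had 27 counts in siMock and 1 in siHNF1B, a ratio of the pooled counts of 49.9 with a 95% interval of 8.23 to 2043. Padi2, a peptidylarginine deiminase (ENSMUSG00000028927; chromosome 4, 140906336 to 140952586), went from 22.9 ± 7.19 to 2.30 ± 0.542 CPM (SD, n = 3 each), with a log2 fold change of −3.36 (SE 0.189). Kif12, a kinesin gene (ENSMUSG00000028357; chromosome 4, 63157948 to 63172145), went from 21.9 ± 0.697 to 2.47 ± 0.915 CPM, with −3.01 (SE 0.192). The aldo-keto reductase genes Akr1b7 and Akr1c19 had log2 fold changes of −3.49 and −2.95 and the sulfotransferase gene Sult1d1 −2.73, though each has close relatives that could share its reads. Aoc1, which encodes diamine oxidase, had −3.35, the hyaluronan link protein gene Hapln1 −3.00 and Phyhipl −2.76. Mkrn2os had −3.24. It is named as the opposite strand of Mkrn2, whose own log2 fold change was −0.11 (SE 0.105). Adjusted p-values of these 10 genes lay between 3.75e-10 and 0.000186 (edgeR). Within the shallow libraries 5 of the 10 had enough counts to be tested, and Padi2 and Kif12 did not pass there, with log2 fold changes of −3.29 (adjusted p = 0.0859) and −3.35 (adjusted p = 0.0669).

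The 10 largest rises were in genes at a mean of 0.892 CPM (that of Aldh1a3) or less in siMock. Adgrf5, an adhesion G protein-coupled receptor gene (ENSMUSG00000056492; mm10 chromosome 17, 43360329 to 43459557), went from 0.159 ± 0.275 to 13.5 ± 0.228 CPM (SD, n = 3 each), with a log2 fold change of 4.89 (SE 0.315). The matrix genes Matn3 (matrilin 3; ENSMUSG00000020583; chromosome 12, 8947929 to 8972028) and Col14a1 (a collagen; ENSMUSG00000022371; chromosome 15, 55307644 to 55520803) had 4.30 (SE 0.324) and 3.63 (SE 0.231). Col14a1 stood at 21.0 ± 3.49 CPM after knockdown. Aldh1a3, an enzyme of retinoic acid synthesis, had 3.57 (SE 0.360). The other 6 had 1 to 3 counts in all siMock libraries together. The pooled ratio, siHNF1B over siMock, was 26.0 (95% interval 4.44 to 1047) for the collagen cross-linking enzyme gene Lox and 24.9 (4.25 to 1004) for Wnt3. It was 22.2 (7.41 to 109) for Rab7b and 16.8 (4.45 to 142) for Col6a3. For the kallikrein gene Klk6, which has close relatives, it was 15.5 (5.13 to 76.7), and for Npy, which encodes neuropeptide Y, 13.3 (4.39 to 66.2). Adjusted p-values of the 10 genes lay between 4.41e-09 and 0.00023 (edgeR). With DESeq2, 9 of the 10 were tested and 6 called, while Lox, Klk6 and Npy were tested and not called. The 10 genes had too few counts to be tested within the shallow libraries, or without siHNF1B replicate 1 or 2. Without siMock replicate 2, the deep siMock library, 1 of the 10 had enough counts to be tested.

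Genes known from the literature as HNF1B targets were lower as a group. Of 14 tested members 9 were lower and 1 higher, Socs3 (9 and 1 adjusted over the list alone), with a median log2 fold change of −0.89. Beside Kif12 these were Cys1, which encodes cystin, at −2.06 (SE 0.143), the potassium channel gene Kcnj16 at −1.96 (SE 0.121) and the apical polarity gene Crb3 at −1.67 (SE 0.149). Kcnj16 went from 120 ± 16.8 to 27.4 ± 2.62 CPM (SD, n = 3 each). The list was lower than other genes by camera, with an adjusted p of 1.72e-06, and with an adjusted p of 0.245 with an estimated correlation. Within the shallow libraries Cys1 had −1.03, Crb3 −2.30, Kif12 −3.35 and Kcnj16 −2.27. Of these, Cys1, Crb3 and Kif12 did not pass there. The list median was −1.39 within the deep and −0.90 within the shallow libraries, where 11 and 4 members were lower. It was −0.46 with the deep libraries thinned (5 of 10 lower), −1.59 with no count filter (12 of 20), −1.45 without siMock replicate 1 (11 of 16) and −1.38 without siHNF1B replicate 3 (11 of 16). Umod, with 1 count in the 6 libraries together, and Fxyd2, with 2, were too low to be tested. The primary cilium and cystic disease list moved in both directions. Of 49 members 6 were lower and 5 higher (6 and 5 adjusted over the list alone). Pkhd1, the gene of autosomal recessive polycystic kidney disease, went from 298 ± 24.6 to 94.0 ± 0.904 CPM, with −1.66 (SE 0.112), and Bicc1 had −0.62 (SE 0.093). The 5 higher members were Dync2h1 at 0.58 (SE 0.135), Ift20, Ift172 and Kif3a, which act in transport along the cilium, and Kif7, a kinesin gene of the ciliary tip. The list did not stand apart from other genes (camera adjusted p = 0.686).

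Many of the epithelial identity genes tested were lower after knockdown. Of 27 members 15 were lower and 1 higher, Ctnnd1 (17 and 1 adjusted over the list alone), with a median log2 fold change of −0.52. The epithelial transcription factor genes Ovol1, Ehf and Grhl1 had −2.10 (SE 0.361), −2.03 (SE 0.248) and −1.76 (SE 0.438), and St14, which encodes the serine protease matriptase, had −1.71 (SE 0.181). Camera gave an adjusted p of 1.39e-07, and an adjusted p of 0.248 with an estimated correlation. Within the shallow libraries Ehf had −0.71 and St14 −2.70, and neither passed. Ovol1 and Grhl1 had too few counts to be tested there. Levels of St14 overlapped between the groups. The median was −0.71 within the deep and −0.68 within the shallow libraries, where 17 and 5 members were lower. It was −0.31 without siMock replicate 2 (8 of 21 lower), −0.40 without siHNF1B replicate 1 (8 of 22), −0.33 without siHNF1B replicate 2 (9 of 22), −0.22 with the deep libraries thinned (5 of 20), −0.34 with no count filter (14 of 33) and −0.59 with DESeq2 (9 of 28). Of 21 tight junction genes 7 were lower and 3 higher, Magi3, Cgn and Cgnl1 (8 and 3 adjusted over the list alone). The claudin genes Cldn6, Cldn2 and Cldn4 had −1.86, −1.32 and −0.84 and Lsr had −0.67, while the list as a whole did not pass the test (camera adjusted p = 0.139).

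The apical-basal polarity list was tested because the series title names cell polarity, so its direction is not independent evidence. Of 33 members 6 were lower and 3 higher, and the list did not pass the test (median log2 fold change −0.11, camera adjusted p = 0.256, fry adjusted p = 0.108). Counts adjusted over the list alone were 7 lower and 5 higher, which is likewise not independent evidence. The motor gene Myo5b went from 19.8 ± 1.52 to 5.67 ± 0.473 CPM (SD, n = 3 each), with −1.70 (SE 0.157). Crb3 (−1.67) encodes a Crumbs protein of the apical membrane. Rab11a, which encodes a GTPase of recycling endosomes, had −1.06 (SE 0.158) and Amot −0.89 (SE 0.127). Within the shallow libraries Myo5b had −1.81 and Crb3 −2.30 and neither passed, while Rab11a had −0.89 and Amot −0.63. The higher members were Msn, Amotl1 and Pard3. Within the deep libraries alone the list passed the threshold (camera adjusted p = 0.049), and within the shallow ones it did not (0.624), with 12 lower and 8 higher in the former and 3 and 2 in the latter. The counts were 13 lower and 9 higher with the depth term, 6 and 6 with limma voom, 5 and 1 with DESeq2 or without siHNF1B replicate 1 or 2, and 3 and 2 with the deep libraries thinned. The median was −0.04 without siMock replicate 2 and −0.02 within the shallow libraries. In the planar cell polarity list 4 of 18 members were lower, Prickle2 at −1.45 (SE 0.442), Vangl2, Intu and Fat1, and 3 higher, Prickle1 at 1.09 (SE 0.122), Ptk7 at 0.71 (SE 0.131) and Dvl2 at 0.49 (SE 0.143). Adjusted over the list alone 4 were lower and 6 higher, and the list did not pass (camera adjusted p = 0.370).

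**Figure D3:**
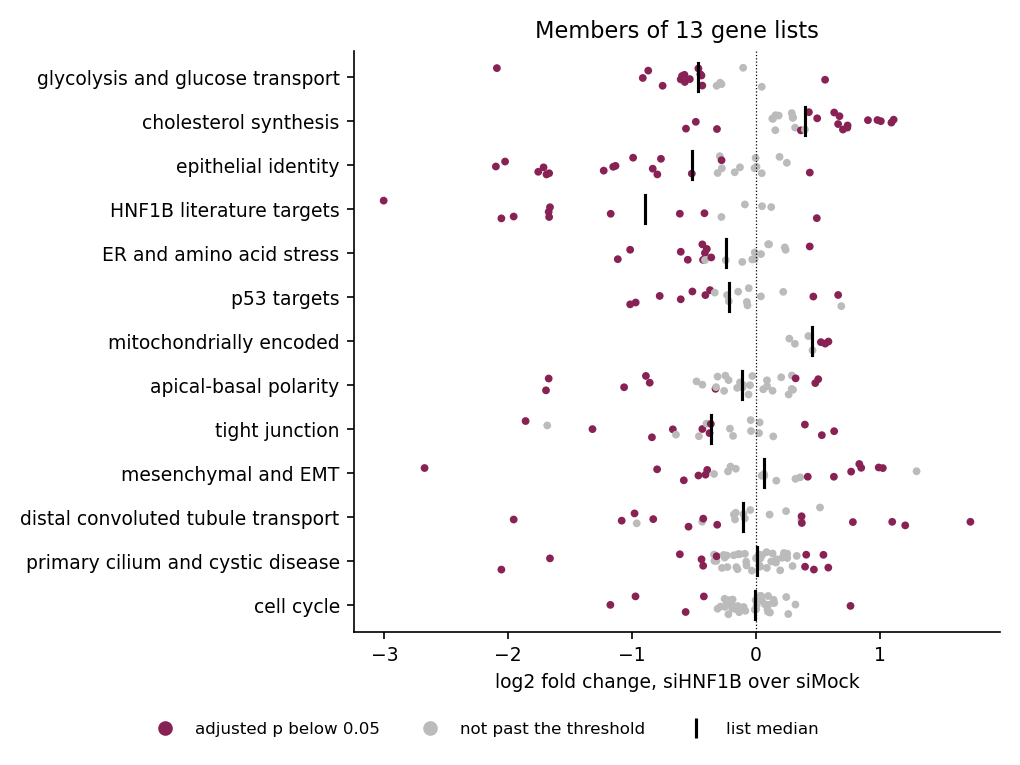
Log2 fold change (siHNF1B over siMock, x axis) of the tested members of 13 gene lists, one point per gene, with called genes in purple, the others in grey and the list median as a black bar. The glycolysis, epithelial identity and HNF1B target lists lie mostly below 0 and the cholesterol synthesis list mostly above it, and the other lists shown spread closer to 0 or to both sides.

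Glycolysis and glucose transport genes were lower together. Of 19 members 13 were lower and 1 higher, Pklr (16 and 1 adjusted over the list alone), with a median log2 fold change of −0.47. The glucose transporter genes Slc2a3 and Slc2a1 had −2.09 (SE 0.223) and −0.87 (SE 0.113). Ldha, which encodes lactate dehydrogenase A, went from 998 ± 47.7 to 522 ± 70.6 CPM (SD, n = 3 each), with −0.91 (SE 0.108), and the hexokinase gene Hk2 had −0.75 (SE 0.110). Camera gave an adjusted p of 1.39e-07, and an adjusted p of 0.245 with an estimated correlation. The median was −0.45 within the deep and −0.64 within the shallow libraries, where 17 and 11 members were lower, and 8 of 18 were lower without siHNF1B replicate 1 or 2. Pklr is the pyruvate kinase form of liver and red cells.

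Cholesterol synthesis genes were mostly higher. Of 27 members 14 were higher and 3 lower (18 and 3 adjusted over the list alone), with a median log2 fold change of 0.39. The sterol enzyme genes Msmo1, Pmvk and Lss had 1.09 (SE 0.150), 1.01 (SE 0.117) and 0.98 (SE 0.115), and Insig1, which encodes a sterol-regulated brake on SREBP, had 1.11 (SE 0.135). Lss went from 141 ± 14.5 to 282 ± 12.7 CPM (SD, n = 3 each). The 3 lower members were Pcsk9, which promotes LDL receptor breakdown, Ggps1, an enzyme of a side branch of the pathway, and Hmgcs1, an early enzyme of it. No member was called lower without siHNF1B replicate 1 or 2, within the shallow libraries, with the deep libraries thinned or with DESeq2. Camera gave an adjusted p of 1.39e-07, and an adjusted p of 0.290 with an estimated correlation. The median was 0.44 within the deep and 0.45 within the shallow libraries, where 19 and 7 members were higher, and 8 of 25 were higher with the deep libraries thinned.

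Some members of the ER and amino acid stress list and some p53 targets were lower, while 11 and 10 members did not pass. In the first, 9 of 21 members were lower and 1 higher, Dnajb9 (10 and 2 adjusted over the list alone). Trib3, a target of ATF4, had −1.12 (SE 0.123), Atf3 −0.61 (SE 0.172) and Ddit4 −0.55 (SE 0.104). Among p53 targets 7 of 19 were lower and 2 higher, Sesn1 at 0.66 (SE 0.122) and Phlda3 (8 and 3 adjusted over the list alone). Ccng1 had −0.97 (SE 0.126) and Rrm2b −0.78 (SE 0.131). Sesn2, a member of both lists, had −1.02 (SE 0.126) over all libraries. Within the shallow libraries Trib3 had −0.25, Sesn2 −0.10 and Sesn1 0.34, and none of the 3 passed. Camera gave adjusted p-values of 0.033 for ER and amino acid stress and 0.041 for p53 targets, and adjusted p = 0.290 for each with an estimated correlation. With the depth term the adjusted p was 0.091 for both. It was 0.094, 0.104 and 0.157 for ER and amino acid stress without siMock replicate 2, siHNF1B replicate 1 and siHNF1B replicate 2, and 0.0883 with the deep libraries thinned. For p53 targets it was 0.073, 0.067 and 0.0505 without siMock replicate 1, siMock replicate 3 and siHNF1B replicate 2, and 0.060 with limma voom. Within the deep libraries it was 0.023 and 0.054, and within the shallow ones 0.419 and 0.088, for the ER and p53 lists in that order.

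Of 7 mitochondrially encoded genes 3 were higher and 0 lower (4 and 0 adjusted over the list alone), namely mt-Nd2 at 0.58 (SE 0.130), mt-Nd5 at 0.56 (SE 0.108) and mt-Nd4 at 0.52 (SE 0.140). Camera gave an adjusted p of 0.041, and an adjusted p of 0.629 with an estimated correlation. It was 0.158 without siMock replicate 2 and 0.111 without siHNF1B replicate 3. Genes of this class also moved with library depth, and mt-Co1 and mt-Nd1 were 0.87 and 0.78 log2 units higher in the shallow libraries. With the depth term the camera adjusted p was 2.86e-07 at the preset correlation of 0.01. That p-value treats the 7 genes as nearly independent, though their estimated correlation was 0.92, so it overstates the evidence. Within the deep libraries mt-Nd2, mt-Nd5 and mt-Nd4 had log2 fold changes of 0.77, 0.66 and 0.69, and within the shallow ones 0.60, 0.57 and 0.61. The log2 fold changes of mt-Nd2, mt-Nd5 and mt-Nd4 with the depth term were 0.73, 0.64 and 0.68. The mitochondrial genes as counted took together 0.898%, 0.535% and 0.765% of counts in siMock replicates 1, 2 and 3 and 0.788%, 0.877% and 1.24% in those of siHNF1B. Of these genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l had 0 counts in every library and mt-Nd3 had 11 in all. The shares thus hold little or nothing of these transcripts. In the cell cycle list 34 of 39 members did not pass the test. The 4 lower members were the cyclin E genes Ccne1 at −1.18 (SE 0.138) and Ccne2 at −0.97 (SE 0.113), Pcna at −0.57 (SE 0.132) and Aurkb, and Ccnd1 was higher at 0.76 (SE 0.157). The counts were 4 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.253).

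Genes of distal tubule ion transport moved in both directions. Of 25 members 7 were lower and 6 higher (8 and 9 adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.347). Beside Kcnj16, the sodium channel subunit genes moved apart, with Scnn1a at 1.73 (SE 0.174) and Scnn1g at −0.83 (SE 0.163). The kinase gene Sgk1 had 1.20 (SE 0.205) and the calcium pump gene Atp2b4 1.10 (SE 0.247). Slc12a3, which encodes the sodium chloride cotransporter that marks the distal convoluted tubule, had 13 counts in the 6 libraries together and was not tested. Among kidney developmental transcription factors, of 22 members 5 were lower and 7 higher (8 and 7 adjusted over the list alone; camera adjusted p = 0.933). Beside Hnf1b itself, Irx3 had −2.04 (SE 0.241) and Foxa1 −1.56 (SE 0.280), Wnt4 and Sall1 were also lower, and Osr1 had 1.59 (SE 0.226).

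Markers of other nephron segments were few above the count filter. All 3 called proximal tubule markers of 5 tested were lower (3 adjusted over the list alone), Ggt1 at −1.54 (SE 0.153), Lrp2 at −0.49 and the water channel gene Aqp1 at −0.35 (SE 0.114), with Aqp1 at 0.17 within the shallow libraries (camera adjusted p = 0.063). Of 5 collecting duct principal cell markers 3 were lower, Avpr2 at −1.17 (SE 0.335), Scnn1g and Hsd11b2 at −0.40 (SE 0.108), and 1 was higher, Tfap2b at 0.37 (SE 0.131), which had −0.04 within the shallow libraries (camera adjusted p = 0.256; 3 and 1 adjusted over the list alone). Of 5 thick ascending limb markers Ppp1r1b was lower at −1.62 (SE 0.147) and Irx1 and Irx2 were higher at 1.24 (SE 0.289) and 0.51 (SE 0.147), again 1 and 2 adjusted over the list alone (camera adjusted p = 0.739). Levels of Irx1 overlapped, with 1.90 CPM in siHNF1B replicate 3 against 0, 3.18 and 3.67 CPM in siMock replicates 1, 2 and 3. Car2, the 1 intercalated cell marker tested, had −0.35 (SE 0.169), which did not pass.

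Among markers of cells from outside the tubule, the fibroblast markers Pdgfrb and Col1a1 were higher at 1.15 (SE 0.367) and 0.99 (SE 0.236), 2 of 4 tested (2 adjusted over the list alone; camera adjusted p = 0.063). Col1a1 stood at 8.68 ± 0.768 CPM after knockdown (SD, n = 3). The macrophage receptor gene Csf1r was lower at −1.38 (SE 0.115), 1 of 2 immune markers (1 adjusted over the list alone; camera adjusted p = 0.253). Flt1 was lower at −1.18 (SE 0.161), 1 of 3 endothelial markers (1 adjusted over the list alone; camera adjusted p = 0.621), and Pecam1 had 1 count in the 6 libraries together. In the mesenchymal and EMT list 6 of 24 members were lower and 7 higher (7 and 9 adjusted over the list alone; camera adjusted p = 0.827). Tgfbi, which encodes a secreted matrix protein, had −2.68 (SE 0.210), and Col5a1 and Thbs1 had 1.02 (SE 0.184) and 0.85 (SE 0.101).

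Signalling and response lists did not pass as groups, though single members moved. Among immediate early genes 6 of 18 were lower and 4 higher (6 and 6 adjusted over the list alone; camera adjusted p = 0.846). Egr1 went from 59.2 ± 5.49 to 164 ± 6.22 CPM (SD, n = 3 each), with 1.38 (SE 0.121), Egr2 had 2.50 (SE 0.468), Fos 1.66 (SE 0.286) and Dusp1 −0.74 (SE 0.143), and Ier2 was also higher. Levels of Fos overlapped between the groups. They were 4.24, 1.99 and 5.50 CPM in siMock replicates 1, 2 and 3. In those of siHNF1B they were 7.13, 7.26 and 1.90 CPM. Of 31 interferon response genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.791), with Stat2 at 0.53 (SE 0.120), Rsad2 at 0.62 (SE 0.199), Tlr3 at 0.49 (SE 0.153) and Ifi27 at −1.17 (SE 0.122). The mean level of Rsad2 over libraries was 9.55 ± 2.16 CPM in siMock and 9.53 ± 3.65 CPM in siHNF1B (SD, n = 3 each). Of 16 NF-kB and inflammatory genes 3 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.827). The chemokine genes Cxcl12 and Cxcl16 had 3.39 (SE 0.325) and 0.88 (SE 0.209), Socs3 was also higher, and Vcam1 and the complement gene C3 had −2.04 (SE 0.458) and −0.77 (SE 0.105). Of 10 canonical Wnt targets Cd44 at 0.90 (SE 0.125), Ccnd1 and Tcf7 at 0.69 (SE 0.213) were higher and Ephb2 at −0.36 (SE 0.107) lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.139). Levels of Ccnd1, Tcf7 and Ephb2 overlapped between the groups. Tcf7 was lower in siHNF1B replicate 3 (1.90 CPM) than in any siMock library. Of 16 reference genes B2m and Gusb were higher, with B2m at 0.94 (SE 0.124), and Hprt at −0.65 (SE 0.175), Gapdh at −0.61 (SE 0.112) and Pgk1 at −0.58 (SE 0.159) were lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.341). These 5 kept their signs under RLE normalization, under library totals only, and with mitochondrial and the most abundant genes left out. The list median, list mean and camera differed in sign for the endothelial, primary cilium, thick ascending limb, interferon response, immediate early and kidney transcription factor lists. With an estimated correlation 0 of the 7 lists called by camera passed, whereas unadjusted p-values under 0.05 remained for the HNF1B target (0.0155), glycolysis (0.0189), epithelial identity (0.0286) and cholesterol (0.0478) lists. Fry, which does not compare a list with other genes, gave adjusted p-values under the threshold for 4 lists that camera did not call, namely distal convoluted tubule transport (0.0296), endothelial (0.0296), fibroblast (0.0444) and cell cycle (0.0492). It did not call the mitochondrially encoded list (0.164), and it called the other 6 lists that camera called.

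The HNF1B ChIP-seq list held 7421 peaks, with a median width of 209 bp (range 146 to 1227). There was 1 ChIP-seq sample, so peaks have no replicate check, and the authors' score per peak is used only to describe and rank peaks within this list. The score had a median of 16.7 and a maximum of 243, and 103 peaks scored at least 100. All positions are mm9. The peak with the highest score lay on chromosome 2 at 26337569 to 26338099 (score 243), followed by chromosome 13 at 4190128 to 4190496 (241), chromosome 7 at 148402201 to 148402614 (223.1), chromosome 2 at 35070509 to 35070862 (223.0) and chromosome 13 at 4232690 to 4233077 (220). A further peak on chromosome 13, at 4278588 to 4278958 with a score of 196, lay near the 2 listed for that chromosome and was picked after the values were seen. What is annotated at these positions was not determined here. Autosomes held 6936 peaks, the X chromosome 465 and the Y chromosome 1. Peaks per Mb, up to the last peak of each chromosome, ranged from 2.25 to 3.88 on autosomes other than 4 and 7 (median 3.04), and stood at 1.21 on chromosome 4 with 189 peaks and at 1.46 on chromosome 7 with 223 peaks.

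**Figure D4:**
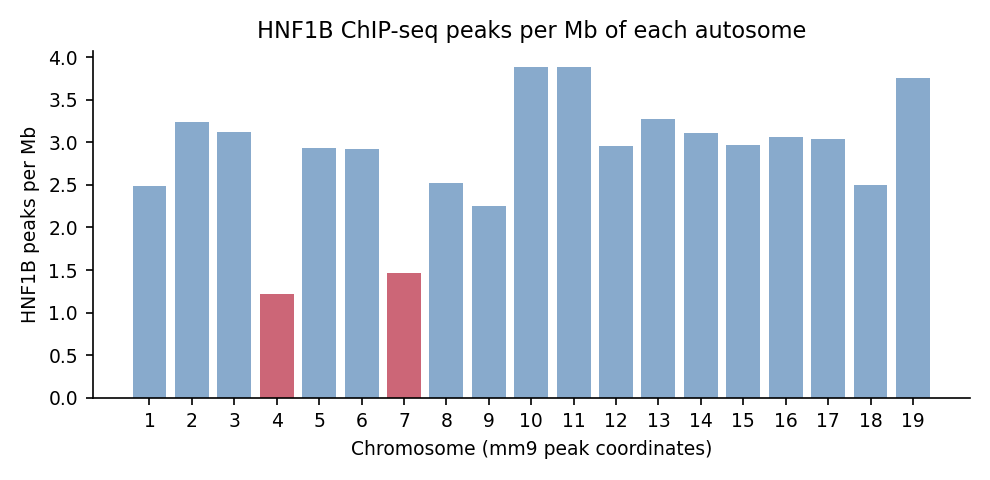
HNF1B ChIP-seq peaks per Mb of each autosome (mm9 coordinates, from position 0 to the last peak). Bars for chromosomes 4 (1.21 per Mb) and 7 (1.46 per Mb), in red, are the lowest of the 19.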

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

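Depth limits these results: of the settings below, the depth term, the fits within deep or shallow libraries and the thinning were chosen after the library totals were seen. The fall of Hnf1b kept its direction and its side of the threshold under all 18 alternatives (log2 fold change −1.67 to −1.15). The number of genes called, 2717, with 1369 lower and 1348 higher, moved by over 1.5 times under 10 of 20. It was 4988 (2453 lower, 2535 higher) with the depth term, 4861 (2445 and 2416) within the deep libraries, 590 (295 and 295) within the shallow ones, 634 (336 and 298) with the deep libraries thinned, 770 (428 and 342) with DESeq2, 1661 (842 and 819) at an adjusted p below 0.01 and 1296 (639 and 657) with at least 1.5-fold. Leaving out each replicate gave 613 to 3214 called, 332 to 1643 lower and 281 to 1571 higher. The fits without siHNF1B replicate 1 (654), siHNF1B replicate 2 (613) or siMock replicate 2 (1522) each lost a deep library and tested 8495 to 8516 genes. Without siMock replicate 2 no siMock library is deep, and 49 of the genes called with all libraries took the other sign. For DESeq2 the cause was not tested, and all of its 770 genes were among the 2717 with the same sign.

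The number of lists called, 7, was 5 to 10 under other settings and 0 with an estimated correlation. The polarity list stayed over the threshold (adjusted p 0.171 to 0.624) except within the deep libraries (0.0491), and the cause was not tested. The glycolysis, cholesterol, epithelial and HNF1B target lists kept their calls under all alternatives but the estimated correlation (adjusted p 0.245 to 0.290), while the stress, p53 and mitochondrial lists lost theirs under 7, 8 and 3 alternatives. Among named genes 2 reversed within the shallow libraries, where neither was called: Tfap2b (−0.0448) and Aqp1 (0.173). Of the others tested there 26 lost their call and 35 kept it. Calls lost and kept numbered 42 and 63 with DESeq2, 17 and 43 without siHNF1B replicate 1, 18 and 42 without siHNF1B replicate 2, 13 and 47 without siMock replicate 2, and 1 and 105 without siMock replicate 1 or 3. Numbers kept, also for the replicate block below, include Car2 where it was tested, though Car2 was not called in any fit. Named genes with too few counts to be tested in a fit are in neither number.

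Whether replicate numbers pair the samples cannot be told, since siMock and siHNF1B libraries of like depth deviated together. Deviations from the group means correlated at −0.23, 0.60 and 0.33 for numbers 1, 2 and 3, and number 1 joins a shallow and a deep library. Correlations were positive in every pair of like depth and negative in every other pair. Among deep pairs the shared number gave 0.60 and the other 0.48, and among shallow pairs 0.33 and 0.30. Not every sample correlated best with its own number. A replicate block gave 2861 genes (1413 lower, 1448 higher) and 7 lists, with 8 named genes losing their call and 98 keeping it, and 8 polarity genes lower and 7 higher. Of the 7421 peaks, the upper part by score held 3710 by construction, with a median width of 242 bp and 0.37 times as many peaks per Mb on chromosomes 4 and 7 as the median of the other autosomes (0.44 for all peaks). Peaks near transcription start sites, with their windows, and motif mismatches were not run, since no mm9 genome or annotation was used here.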

Other observations

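The tests of the grouping and of the depth classes on the number of genes, the score comparisons of peaks, the parts of chromosome 9, and the lists of fatty acid synthesis genes, HIF targets and LXR targets were chosen after the main results were seen, and the interval used for the parts of chromosome 4 replaced a rule on the permutation p after its value was seen, with no change of verdict. Fatty acid synthesis genes, the other branch of SREBP-driven lipid synthesis, were higher for 5 of 13 members and lower for 0, with a median log2 fold change of 0.19 (camera p = 0.0128, and p = 0.0788 with an estimated correlation). Elovl5 had 0.71 (SE 0.133), Fasn, the fatty acid synthase gene, 0.70 (SE 0.118), and Acly and Acaca 0.55 (SE 0.122) and 0.53 (SE 0.111). Fads2 was the remaining member called, at 0.40 (SE 0.102).

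The shallow libraries differed from the deep ones in which RNAs they held. With group and depth class in the same model, 1659 genes differed by depth class, 841 higher and 818 lower in the shallow libraries. Rn7sk was 2.95 log2 units higher there, S100a6 0.99 and Actb 0.60, while the basement membrane genes Col4a2 and Hspg2 were 0.72 and 0.61 lower (these 5 were picked after their values were seen, among the 20 genes with the smallest p). The effect of knockdown itself differed between the depth classes for 1 of 12143 genes, Tpd52 (named for that reason, interaction adjusted p = 0.034 by edgeR), at −1.19 in the deep and −3.45 in the shallow libraries. At an unadjusted p under 0.05 there were 557 genes, fewer than chance alone would give at that threshold. Only 1 siMock library was deep and 1 siHNF1B library shallow, so this test had little power. The few calls therefore do not show that the effect was alike in both classes.

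The number of genes called, 2717, was the highest among the 10 ways to split the 6 libraries 3 against 3, and 1 of 10 splits gave as many. The highest of the others was 413, from siMock replicate 1 with siHNF1B replicates 1 and 2, and the split by depth class gave 4. In each of the other splits a side mixed siMock and siHNF1B libraries. The difference between the groups then adds spread within sides and can lower the number called. The split by depth class gave 4, though 1659 genes differed by depth class with group in the model. Those numbers thus do not show what chance gives. With 10 splits no share under 0.05 can be reached. A depth term raised the number to 4988 and kept 2716 of the 2717 genes, and all 2717 kept their sign. Such a term also takes up spread between libraries, since 1659 genes differed by depth class, and this can raise the number by itself. The rise therefore does not decide whether the unequal number of deep libraries in the groups contributes to the number. The signs kept argue against it as the source of the direction of these genes.

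The lower glycolysis genes were weighed against technical and biological explanations. An unequal number of deep libraries is argued against, since the list median stayed at −0.45 or further from 0 with a depth term, within the deep and within the shallow libraries. Gene span had little bearing on fold change over all genes (r = 0.047 with log span), and removing a trend with span and abundance left −0.48. There was thus little span trend to remove, and such a trend is argued against for that reason. Lower activity of HIF, the hypoxia-inducible factor that drives glycolysis genes, is a candidate explanation as a hypothesis: 8 of 24 HIF targets outside glycolysis (1 of the 8, Ddit4, also in the stress list) were lower, Bnip3 at −0.84 (SE 0.103) and Slc16a3 at −0.87 (SE 0.160) among them, and 1, Lox, was higher, with a list median of −0.25 (camera p = 0.000214, but p = 0.0773 with an estimated correlation). Differences in cell density, glucose or oxygen between wells were not tested and stay open.

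The higher cholesterol synthesis genes were weighed in the same way. The list median was 0.44 or more with the depth term and within each depth class, so unequal depth does not explain the shift. It was 0.39 both before and after a trend with gene span and abundance was removed. Fold change hardly followed span over all genes (r = 0.047), so there was little span trend that could explain the shift. Low cell sterol, which would turn SREBP2 on and LXR off, cannot be told apart from other causes, because the LXR targets went both ways (median 0.068 over 5 tested). Abca1 and Arl4c had −0.70 (SE 0.101) and −1.04 (SE 0.110), and Mylip and Lpcat3 had 0.92 (SE 0.125) and 0.66 (SE 0.116).

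Fewer HNF1B peaks per Mb on chromosomes 4 and 7 do not follow the number of annotated genes, as peaks per 100 RefSeq genes there averaged 0.361 times the median of the other autosomes. A lower DNA copy number may contribute, as a hypothesis, since in siMock RNA the median log2 CPM of tested protein-coding genes was 4.69 on chromosome 4 and 4.66 on chromosome 7, below the lowest of the other autosomes (5.14), and over the 19 autosomes peaks per Mb and that median had r = 0.87 (permutation p = 2e-05) and rho = 0.78 (permutation p = 0.00012), or r = 0.67 (permutation p = 0.0034) without chromosomes 4 and 7. Peak scores do not decide it. The median score of all peaks there minus that of the other autosomes was −2.06. With the chromosome as the unit, the mean of their chromosome medians minus that of the others was −2.40. Of 171 pairs of autosomes 9 lay as far from the rest in either direction (exact permutation p = 0.0526, two-sided). Chromosomes 7 and 4, at 14.4 and 15.4, nevertheless stood below the lowest of the others (15.6). Over the first 110 Mb of chromosome 4 peaks stood at 0.845 per Mb against 2.75 in the last part (mm9). RNA medians of the like-named parts on mm10 were 4.73 and 4.71, a difference of 0.023 (95% bootstrap interval −0.33 to 0.39). Both medians lay below those of the other autosomes, though the last part had peaks within their range (2.25 to 3.88 per Mb). Low RNA and few peaks thus did not go together within chromosome 4. An RNA fall of over 0.33 in the first part lies outside the interval, and a smaller one cannot be told from none. Over the first 35 Mb of chromosome 9 peaks stood at 1.37 against 2.66 per Mb. RNA medians there differed by −0.15 (−0.59 to 0.26), so a loss of that part cannot be told from none. Gene content differs between chromosomes and no cells of known karyotype were compared, which leaves a different make-up of these chromosomes open.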
